A study of Drosophila melanogaster with 12 samples.

How the data were processed

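RNA was measured in heads of adult Drosophila melanogaster of 2 genotypes, 6 libraries each. Control flies carried the pan-neuronal driver Elav-Gal4 alone, and tau flies carried the driver with UAS-tauR406W, which makes neurons produce human tau with a mutation found in inherited frontotemporal dementia. Per the labels' protocols, flies were collected at day 10 of adulthood, and each library came from 18 pooled heads of both sexes. The pools were described by the submitters as biologically independent. Stranded libraries were made with a NuGen kit that removes ribosomal RNA, and were sequenced as read pairs on an Illumina instrument.

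The table analysed here holds 1 normalised value per gene and library. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, inspected with FastQC and quantified with Salmon 0.13.1, with genome build dm6. Per the file headers, the Salmon results of a pair of sequencing lanes were joined for each library. The deposited values are a signal per gene, made by the authors with DESeq2 1.24 by dividing gene counts by normalisation factors, per the file's name and the submitters' processing notes. The transcript annotation, the step from transcripts to genes and any filter on rows are not given in the sources used here. Low values in each library piled up at multiples of 1 step, the value of 1 read pair, but the step differed between genes. Whole read counts were therefore not recovered, and no count model was used. Dividing each library's total by its step gave an estimate of depth. The estimates ran from 20.1 to 33.1 M read pairs in the controls and from 25.8 to 41.5 M in the tau libraries, and totals of the deposited values ran from 24.65 to 30.24 M. A library's value of 1 read pair, 0.641 to 1.506, sets how finely low genes can be told apart.

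The table has 13515 rows. Symbols for 13432 gene identifiers came from a gene name table, 1 more from a RefSeq table, and 82 had no name. Positions are those of the Ensembl annotation of BDGP6, which has the coordinates of dm6. Genes with a mean value of at least 10 over the 12 libraries were tested, 10845 in all. Values were analysed as log2(value + 1), so that fold changes of low genes are understated. An exact 0 can be a failed estimate where copies of a gene share reads: Prosalpha1, a core subunit of the proteasome, was listed at 0 in 4 controls and 1 tau library. Genes with such values are described by the range of their libraries.

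The comparison of tau with control was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend), with no covariate, and p-values were adjusted by the Benjamini-Hochberg method. Tests were two-sided, and a gene was called at an adjusted p under 0.05. SE is the moderated standard error of the log2 fold change. Gene lists, 46 in all, were tested with limma's camera with its preset correlation of 0.01 between genes, adjusted over the 44 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move on balance in one direction, and does not compare them with other genes. Lists for small nuclear and nucleolar RNAs and for ribosomal RNA had fewer members in the table and were not tested. A misfit member was kept in the nonsense-mediated decay list, CG2846, which encodes riboflavin kinase, and Hsf stood in the heterochromatin list because of its spelling. Markers of the sex of the pooled heads, Yp1, Yp2, Yp3 and fit, were compared with exact two-sided permutation tests over all assignments of the libraries, adjusted over these 4 genes. The smallest p these can give is 0.00216.

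Named genes followed a rule. It took endogenous tau, w, the sex markers, the 12 largest rises and 12 largest falls among called genes without overlap between groups and with a mean of at least 50 in the higher group. It also took the 4 members with the smallest adjusted p of each list that was called or had at least 3 called members, and up to 2 of other lists. Groups, tests, lists and this rule were fixed before the data were examined. A gene that the rule picked is not reported here.

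Alternatives changed the pseudocount, the filter, the scaling and the variance model, added a replicate block or array weights, or left out each library in turn. A covariate from the male RNAs roX1 and roX2 could not be used, because neither has a row here. Called genes next to each other along the chromosomes were counted against 1000 random draws, and again without pairs of one gene family. The question whether called genes cluster was fixed beforehand, the bound and the count without families after the data had been seen. Added after the data had been seen were a fit without 3 libraries with reads in silent genes, a subtraction of that background, and the mean of Yp1, Yp2 and Yp3 as a covariate. Silent genes were the 1969 genes with a median of at most 2 over the libraries. The fit was tested on simulated data with the real genes' means, depths and spread, in which 200 genes per run were changed over 5 runs of the comparison of tau with control, with 10828 genes in the step on average. It recovered 8.9% of genes changed 1.5-fold, 57.6% of those changed 2-fold and 86.2% of those changed 4-fold, and 3.7% of calls were false. Simulated genes varied independently of each other, so these rates may not hold for the real libraries. Figures were drawn with matplotlib 3.10.9.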

Results

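Head RNA of flies that express mutant human tau in neurons was compared with that of driver-only controls at day 10 of adulthood. There were 6 control and 6 tau libraries, each from 18 pooled heads of both sexes. Estimated depth ran from 20.1 to 33.1 M read pairs in the controls and from 25.8 to 41.5 M in the tau libraries. Pearson correlations of log2 values between libraries of a group, across genes, ran from 0.921 to 0.968 in the controls and from 0.908 to 0.966 in the tau group. Control E, control F and tau B held reads in genes that were silent in most libraries, at 8.87, 6.27 and 24.7 estimated reads per kb of exon, against 0.964 to 2.71 in the other 9. They listed 433, 484 and 195 genes at 0, where the others listed at least 1492.

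**Figure D1:**
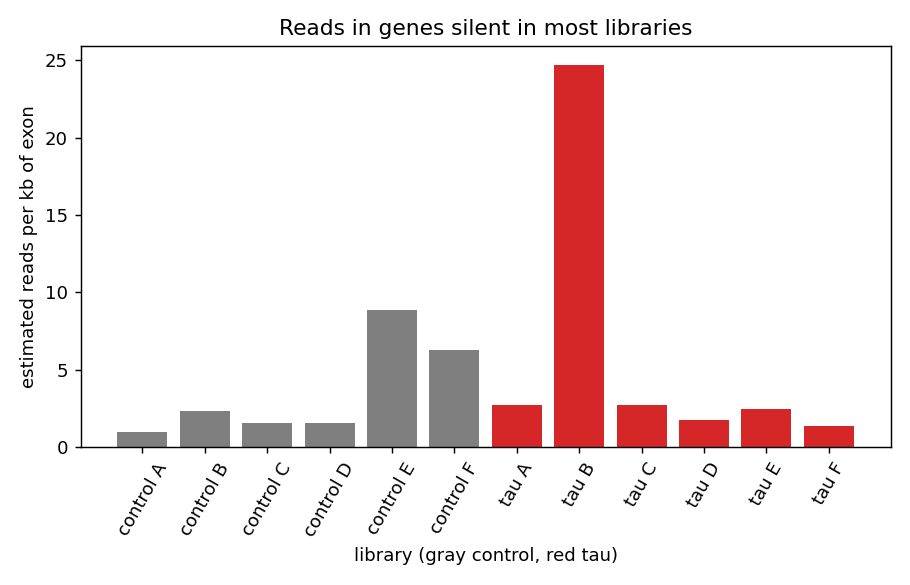
Estimated reads per kb of exon (vertical axis) in 1969 genes silent in most libraries, for each of the 12 libraries (horizontal axis; gray bars are control, red bars are tau). The bars of control E, control F and tau B reach 8.87, 6.27 and 24.7, and the other 9 lie at 2.71 or less.

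The comparison asked which genes differ in level between heads with and without neuronal tau. Of 10845 genes tested, 567 were called: 228 were higher in tau and 339 were lower. A change of at least 2-fold was seen in 172 of these, 60 higher and 112 lower. The values of the 6 tau and 6 control libraries did not overlap for 366 tested genes (3.37%), where chance gives 0.22%. The genes with the most extreme falls included a lens cuticle protein, enzymes of fatty acid metabolism and the female peptide fit, and several of the most extreme rises were cytochrome P450 genes. Of 78 P450 genes, however, 5 rose and 16 fell, and reads of some are treated as uncertain between similar copies. Of the fixed lists, 8 of 16 haemocyte markers and 4 of 24 fat body markers fell, and 6 of 31 antimicrobial peptide genes and 5 of 26 heat shock and chaperone genes rose. None of these lists was called with an estimated correlation (adjusted p = 0.109, 0.275, 0.685 and 0.275). The median log2 fold change of all genes was 0.008. When each library was rescaled to the same total, this median became 0.112, and 525 genes were called higher and 261 lower, so that 66.8% of calls were rises instead of 40.2%. Without control A, 376 genes were called (222 lower), and without tau C 147 were called higher. Without control E, control F and tau B, 308 genes were called, of which 280 were among the 567. With the yolk protein genes as a covariate, 146 were called. That covariate itself differs between the genotypes and takes part of their difference by construction. Losses with it, here and below, therefore do not tell a sex difference from an effect of tau.

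**Figure D2:**
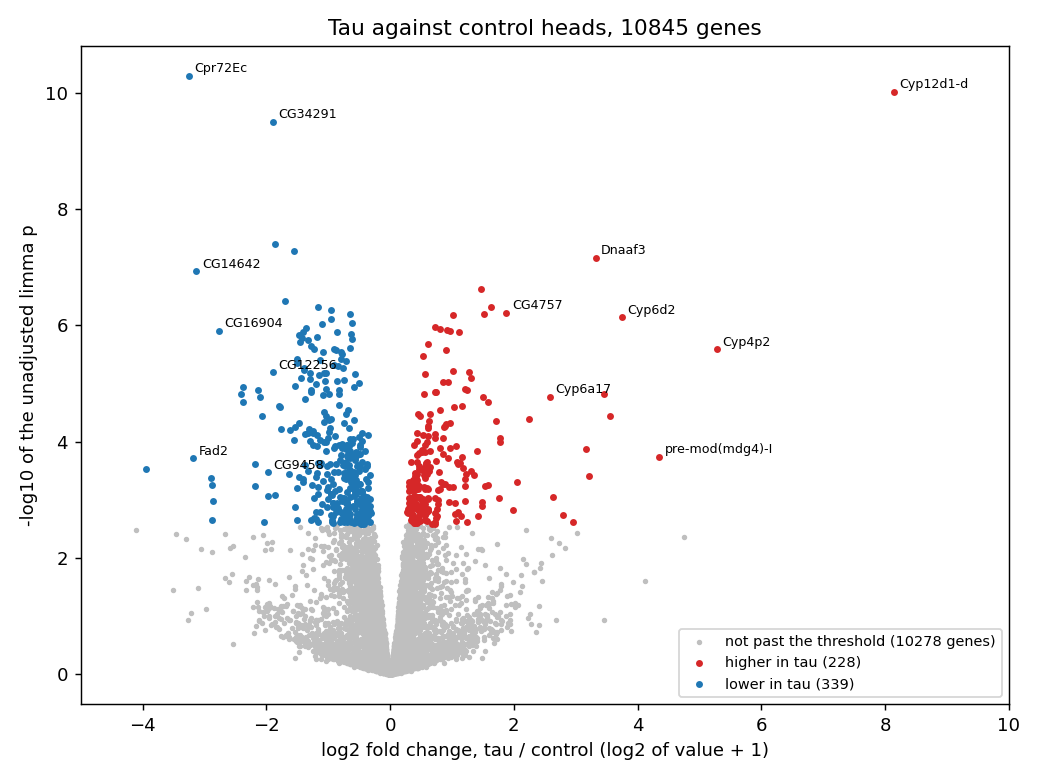
Log2 fold change of tau over control (horizontal axis, from log2 of value + 1) against −log10 of the unadjusted limma p (vertical axis) for 10845 genes. Red points are the 228 genes called higher, blue points the 339 called lower and gray points those not called. Cpr72Ec, at −3.25, has the smallest p.

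Cpr72Ec (FBgn0036619; 3L, 16365894 to 16367340), a cuticle protein of the corneal lens, fell 9.53-fold, from 11493 ± 895 to 1294 ± 572 normalised counts (SD, n = 6 per group). Its log2 fold change was −3.25 ± 0.21 (SE; adjusted p = 5.2e-07). Fad2 (FBgn0029172; 3L, 11023535 to 11024846), a desaturase that makes female pheromones, fell 9.08-fold (−3.18 ± 0.66, adjusted p = 0.00982), and its call was lost without control E, control F and tau B (adjusted p = 0.0852). The predicted fatty acid elongases CG16904, CG30008 and CG9458 had log2 fold changes of −2.77, −2.37 and −1.97 and fell. Cyp4g1 (FBgn0010019; X, 467057 to 469335), the P450 that makes cuticular hydrocarbons, fell 4.30-fold, from 49725 ± 10986 to 13329 ± 7648. CG34291 (3R, 26425290 to 26425781) fell 3.72-fold with little spread, from 1639 ± 337 to 437 ± 62.2 (adjusted p = 1.15e-06). CG14642, CG3513, CG7910 and CG12256 fell 8.77-fold, 5.19-fold, 4.40-fold and 3.70-fold. With the yolk protein covariate, the calls of CG3513 and CG9458 were lost (adjusted p = 0.0538 and 0.0921).

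Among the largest rises outside the P450 genes, Dnaaf3 (FBgn0034352; 2R, 18452737 to 18454462), a predicted assembly factor of axonemal dynein, rose 10.0-fold, from 16 ± 6.72 to 166 ± 54.2 (adjusted p = 0.000123). CG4757 (3R, 11161207 to 11163498) rose 3.67-fold, from 619 ± 165 to 2357 ± 810. CG14275 and CG17325 rose 3.09-fold and 3-fold. CG33093 and net, a transcription factor of wing vein patterning, rose from low levels, 4.72-fold and 2.99-fold. The call of net was lost without the variance trend and with the yolk protein covariate (adjusted p up to 0.235). pre-mod(mdg4)-I was listed at 0 in 3 controls and at most at 26.0 in the others, and lay between 30.3 and 213 in the tau libraries. Its exons are used by trans-splicing with mod(mdg4) transcripts, so its reads are uncertain, and its call was lost with background subtraction or the yolk protein covariate (adjusted p up to 0.111).

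**Figure D3:**
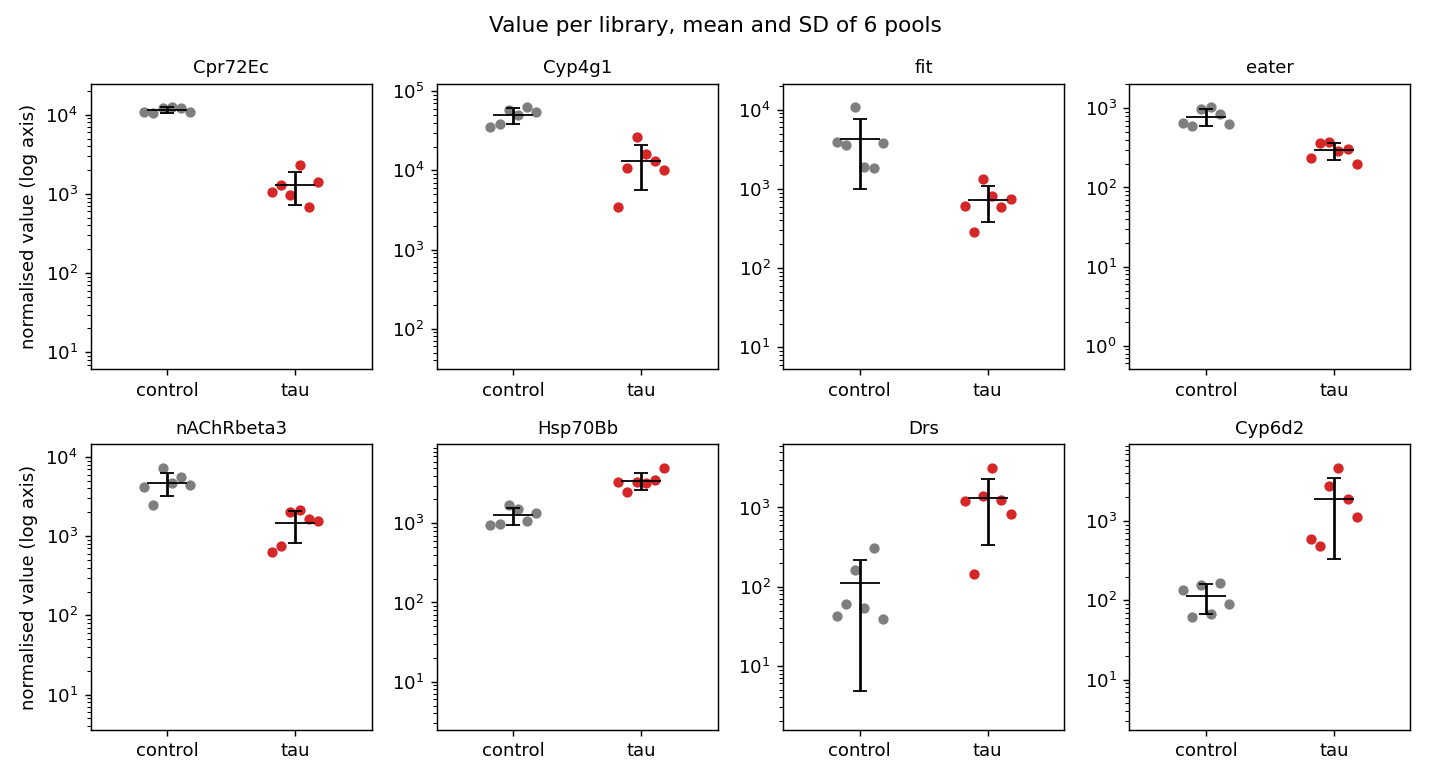
Normalised value per library (vertical axis, log scale) of 8 genes in the control and tau groups (horizontal axis). Points are the 6 libraries of a group, and bars are their mean ± SD. Cpr72Ec lies at 1294 in tau against 11493 in controls on average, and Cyp6d2 at 1926 against 113.

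Of 78 cytochrome P450 genes tested, which encode enzymes of hormone, lipid and xenobiotic metabolism, 5 rose, 16 fell and 57 were not called, and 29 passed when adjusted over the list alone. Cyp6d2 (2R, 22652573 to 22654530) rose 13.4-fold, from 113 ± 46.1 to 1926 ± 1592 (adjusted p = 0.00046). Cyp12d1-d (FBgn0053503; 2R, 11123658 to 11125647) was listed at 0 in 5 controls and at 6.1 in control C, and at 231 to 625 in the tau libraries (adjusted p = 5.2e-07). Cyp4p2 was listed at 0 in 3 controls and at up to 13.2 in the others, against 51.7 to 176 in tau (adjusted p = 0.000653). Cyp6a17 rose 5.98-fold and Cyp4ac2 fell 1.95-fold. The near-identical neighbour Cyp12d1-p, named after its value was seen, had 781 ± 347 and 663 ± 101 in controls and tau (adjusted p = 0.83). The sum of both copies differed by 0.55 ± 0.28 on the log2 scale (exact permutation p = 0.0823). Cyp6a23, the neighbour of Cyp6a17 and also named after its value was seen, fell by 0.55 (adjusted p = 0.0181), and the sum of Cyp6a17 and Cyp6a23 differed by 0.09 ± 0.15 (exact permutation p = 0.528). Reads of these copies are therefore treated as uncertain, though the sequence identity of the copies was not checked. The list's median was −0.17 (camera adjusted p = 0.00175), but adjusted p = 0.899 with an estimated correlation, 0.102 without control E, control F and tau B and 0.0569 with array weights. It was −0.06 when libraries were rescaled to equal totals and −0.30 with the yolk protein covariate.

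Across the 44 lists, 13 were called by camera with its preset correlation, 5 higher and 8 lower. With an estimated correlation none was called at an adjusted p under 0.05, and 7 had an unadjusted p under 0.05, while fry called 9. Other splits of the 12 libraries gave as many called lists often: 55 of 100 splits, the real one included, gave 13 or more. Camera's list calls below are therefore given beside the calls of single members.

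**Figure D4:**
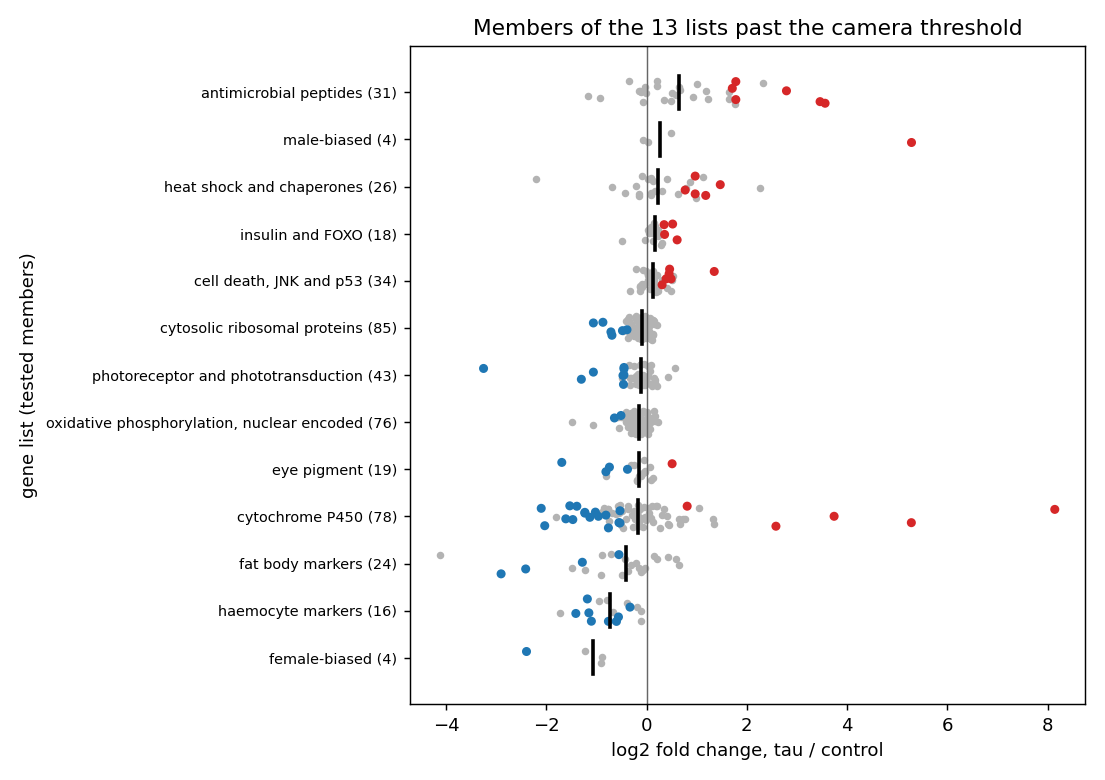
Log2 fold change of tau over control (horizontal axis) for the members of the 13 lists called by camera (vertical axis, number of tested members in brackets). Red and blue points are members called higher and lower, gray points are members not called, and black bars are medians, from −1.07 in the female-biased list to 0.64 in antimicrobial peptides.

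All 16 haemocyte markers, genes of fly blood cells, had values below 0, with a median of −0.72. Of these, 8 fell and 8 were not called, and 11 passed when adjusted over the list alone. The phagocytosis receptor eater fell 2.66-fold, from 787 ± 189 to 296 ± 72.2 (adjusted p = 0.000495), and the scavenger receptor Sr-CI 2.14-fold. The prophenoloxidase PPO2 fell 2.21-fold and the collagen gene vkg 1.52-fold. The list was called by camera (adjusted p = 3.67e-12) and fry (adjusted p = 0.00118), but adjusted p = 0.109 with an estimated correlation. Of 24 fat body markers, 4 fell and 20 were not called, with a median of −0.40 and 8 past the threshold when adjusted over the list alone. The lipoprotein receptor LpR2 fell 2.43-fold, the trehalase gene Treh 1.47-fold and the glucosidase gene tobi 7.46-fold, and the fourth was fit. Camera gave an adjusted p of 0.000132, against adjusted p = 0.275 with an estimated correlation. The median shrank to −0.16 with the yolk protein covariate (adjusted p = 0.046), whose 3 genes are among the 24. With the yolk protein covariate the calls of vkg, Treh and tobi were lost (adjusted p = 0.0685, 0.117 and 0.237), Treh also without control E, control F and tau B (0.0723) and tobi without the variance trend (0.0621).

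The yolk proteins and fit are made mainly in female fat body. fit (3R, 21883924 to 21884454) fell 5.31-fold, from 4274 ± 3282 to 732 ± 350, with an exact permutation p of 0.00216, the smallest these libraries can give (adjusted 0.00866). Yp2 fell by 1.22 on the log2 scale (exact permutation p = 0.0238, adjusted 0.0476). Yp1 and Yp3 differed by −0.91 and −0.89 and did not pass this test, which takes the libraries as unpaired (exact permutation p = 0.0996 and 0.0671, adjusted 0.0996 and 0.0895). In this unpaired test all 4 passed without control E or without tau A, and 1 passed without control A, control B, control C, control F or any of tau B to tau F. With same-letter libraries as pairs all 4 passed an exact sign-flip permutation test (exact permutation p = 0.0312 each). Across all genes, though, same-letter libraries did not pair. By limma over all genes Yp2 did not pass (adjusted p = 0.0706), but did without control D or control E (0.0493 and 0.0214). Of the 4 members of this female-biased list, 1 was called by limma and 4 when adjusted over the list alone, with a median of −1.07 (camera adjusted p = 0.000878, and adjusted p = 0.339 with an estimated correlation). Of 4 male-biased genes, Cyp4p2 rose, while msl-2 and to had log2 fold changes of 0.03 ± 0.09 and −0.08 ± 0.24, and CG13360 of 0.48 ± 0.15 (adjusted p = 0.069, and 0.0214 without control C). That list's median was 0.26 and 2 members passed when adjusted over the list alone. Its camera call (adjusted p = 0.0442) was lost with an estimated correlation (adjusted p = 0.275), at a mean of at least 100 (median 0.03, adjusted p = 0.517), with a pseudocount of 0.5, rescaling to equal totals, a replicate block or no variance trend (adjusted p from 0.0508 to 0.0678), without control E, control F and tau B (median 0.17, adjusted p = 0.121) and without control B, control D, control F, tau B or tau E (adjusted p from 0.0523 to 0.108).

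Of 31 antimicrobial peptide genes, 6 rose, 25 were not called and none fell, and 6 passed when adjusted over the list alone. The antifungal peptide gene Drs rose 11.8-fold, from 111 ± 106 to 1324 ± 992 (adjusted p = 0.00344). The Bomanins, short peptides of the Toll response, included BomBc1, which rose 11-fold, BomBc3 (3.26-fold) and BomS3 (3.44-fold, to 79002 ± 41575). The list's median was 0.64 (camera adjusted p = 0.000132), but adjusted p = 0.685 with an estimated correlation and 0.261 by fry. In tau B the mean log2 value of the list was 9.15, against 10.44 to 10.88 in the other tau libraries, and in the controls it ran from 8.85 in control F to 10.13 in control C and 10.82 in control E. The median of the log2 fold changes was 1.04 without tau B, 1.02 without control E, control F and tau B, and 0.31 with the yolk protein covariate. The calls of BomBc1, Drs and BomS3 were lost with the yolk protein covariate (adjusted p = 0.0517, 0.076 and 0.125). Among 33 genes of immune recognition and signalling, 4 rose and none fell (10 when adjusted over the list alone), and the list was not called (median 0.09, adjusted p = 0.152). PGRP-LF rose 2.31-fold and the NF-kappaB factor dl 1.29-fold, with Tab2, a partner of the kinase Tak1, at a log2 fold change of 0.31 and PGRP-LB at 1.37-fold. PGRP-LB was lost without any single library except tau A (adjusted p from 0.0518 to 0.112), and with the yolk protein covariate all 4 were lost (adjusted p from 0.189 to 0.436). In the Turandot and JAK-STAT list of 11 genes, 3 fell and none rose (6 when adjusted over the list alone), and the list was not called (median −0.48, adjusted p = 0.15). TotC fell 7.30-fold, TotA 3.62-fold and the transcription factor Stat92E 1.40-fold, while the cytokine gene upd3 had a log2 fold change of 1.72 ± 0.54 (adjusted p = 0.0808, and 0.00829 without control C). TotA was lost without control A, control E or tau F (adjusted p up to 0.0619), TotA and TotC without control E, control F and tau B (0.076 and 0.122), and Stat92E with the yolk protein covariate (0.182). TotA and TotC were also lost without the variance trend.

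Of 26 heat shock and chaperone genes, 5 rose, 21 were not called and none fell (7 when adjusted over the list alone). The small heat shock genes l(2)efl, Hsp22 and Hsp26 rose 1.96-fold, 1.96-fold and 2.27-fold. Hsp70Bb rose 2.76-fold, from 1256 ± 315 to 3461 ± 820 (adjusted p = 0.000314). The 6 Hsp70 copies share reads, so which copy rose is uncertain, and their sum was higher by 0.90 ± 0.27 on the log2 scale (exact permutation p = 0.0108). Hsp22 and Hsp26 were lost with the yolk protein covariate (adjusted p = 0.0708 and 0.237). The list's median was 0.23 (camera adjusted p = 0.000256, fry adjusted p = 0.0237, and adjusted p = 0.275 with an estimated correlation), and it was 0.15 without tau D, 0.13 without tau E, 0.11 with the yolk protein covariate and 0.37 without control E, control F and tau B. In the unfolded protein response list of 24 genes, 5 fell and 1 rose (7 when adjusted over the list alone), and the list was not called (median −0.09, adjusted p = 0.0671). The lectin chaperone Cnx99A fell 1.49-fold, Der-1 1.58-fold and Edem2 1.27-fold, and Thor, the translation inhibitor 4E-BP, rose 1.52-fold. Edem2 was lost without any single library except control B and tau D (adjusted p from 0.052 to 0.0799).

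Of 18 genes of the insulin and FOXO list, 4 rose, 14 were not called and none fell (7 when adjusted over the list alone). REPTOR rose 1.28-fold, Thor 1.52-fold, the insulin receptor InR 1.44-fold and the kinase gene Akt 1.27-fold. The median was 0.16 (camera adjusted p = 0.00024, fry adjusted p = 0.0216, and adjusted p = 0.275 with an estimated correlation), and 0.26 when libraries were rescaled to equal totals. REPTOR was lost without control A (adjusted p = 0.0544), Thor without control A, control C, control D, tau A, tau C or tau D (up to 0.0669), InR without control A, control B, control C, tau C, tau D, tau E or tau F (up to 0.0868), and Akt without control A, control C, control F, tau C, tau D, tau E or tau F (up to 0.0928). With the yolk protein covariate all 4 were lost (adjusted p from 0.151 to 0.482). REPTOR, Thor and Akt were also lost without control E, control F and tau B. Thor, InR and Akt were lost without the variance trend, and Akt with each library recentred on its median. Of 34 genes of cell death, JNK and p53 signalling, 6 rose, 28 were not called and none fell (8 when adjusted over the list alone). The DNA end-binding gene Ku80 rose 2.55-fold, from 132 ± 58.1 to 306 ± 40.6 (adjusted p = 0.0143). The matrix protease Mmp1 rose 1.38-fold, rad50 1.37-fold and the caspase inhibitor Diap1 rose by 0.31 on the log2 scale. The median was 0.13 (camera adjusted p = 0.00261, and adjusted p = 0.275 with an estimated correlation), and it was 0.06 without control C, 0.08 with array weights and 0.24 with rescaling to equal totals. Leaving out tau C or tau F ended the call of rad50 (adjusted p up to 0.053), and leaving out control A, control B, control D, tau C, tau D, tau E or tau F that of Diap1 (up to 0.0731). Mmp1, Ku80, rad50 and Diap1 were lost with the yolk protein covariate (adjusted p from 0.166 to 0.261).

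Of 43 genes of the photoreceptor and phototransduction list, which also holds lens proteins, 8 fell, 35 were not called and none rose (15 when adjusted over the list alone). Besides Cpr72Ec, these were led by retinin, another lens protein (2.47-fold), the retinol dehydrogenase Pdh (2.09-fold) and the carotenoid receptor santa-maria (1.37-fold), whose call was lost without control E, control F and tau B (adjusted p = 0.0734). The genes retinin, Pdh and Cpr72Ec lie near each other on 3L, starting at 16331933, 16353233 and 16365894. Their falls may therefore not be independent of each other, and a local difference between strains was not excluded. The list's median was −0.11 (camera adjusted p = 0.000132, fry adjusted p = 0.0237, and adjusted p = 0.381 with an estimated correlation), and it was −0.07 without tau D, −0.17 without control C, −0.06 with the yolk protein covariate (adjusted p = 0.0466) and −0.01 when libraries were rescaled to equal totals. Of 19 eye pigment genes, 4 fell and 1 rose (5 when adjusted over the list alone). The pteridine enzyme se fell 3.23-fold, from 1014 ± 341 to 306 ± 74.5 (adjusted p = 0.000455), v fell 1.76-fold and bw 1.67-fold. The pigment transporter w, which is carried as a marker by most fly transgenes, rose 1.42-fold (adjusted p = 0.0297). The median was −0.16 (camera adjusted p = 0.0162, and adjusted p = 0.275 with an estimated correlation, 0.0519 without tau B, 0.287 with the yolk protein covariate). It was −0.06 with that covariate, −0.10 with array weights and −0.05 with rescaling to equal totals. The call of v was lost without control A, control E, tau E or tau F (adjusted p up to 0.0632), that of bw without control A, tau C or tau F (up to 0.0647), and that of w without control A, control C, control E, control F, tau E or tau F (up to 0.0783). All 3 were lost with the yolk protein covariate (adjusted p from 0.291 to 0.328). Among 54 cuticle protein genes, 3 fell and 1 rose (5 when adjusted over the list alone), and the list was not called (median 0.19, camera direction lower, adjusted p = 0.724). Cpr49Ag fell 2.93-fold. Cpr49Af was listed at 0 in 2 tau libraries and its call was lost without any single library except tau B and tau D (adjusted p from 0.0527 to 0.104), and Acp1 rose 3.38-fold but was lost without tau B, tau D or tau E (up to 0.0649). Cpr49Af and Acp1 were also lost without the variance trend, and without control E, control F and tau B. With the yolk protein covariate both were lost too (adjusted p up to 0.394).

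Lists of neuronal genes other than the photoreceptor list were not called. The 13 pan-neuronal markers had a median of 0.01 and no called member (camera adjusted p = 0.861), with nSyb at −0.24 ± 0.12 and jeb at 0.33 ± 0.18. The 34 synaptic vesicle and active zone genes had a median of 0.01 and no called member (adjusted p = 0.937). Endogenous tau was at 7583 ± 1390 in controls and 6946 ± 285 in tau (−0.10 ± 0.11, adjusted p = 0.713), and the 18 genes of its list held no called member (adjusted p = 0.842). Single genes of such lists were called, but which cells of the head these changes lie in was not tested. The nicotinic receptor subunit nAChRbeta3 fell 3.44-fold, from 4753 ± 1566 to 1455 ± 636 (adjusted p = 0.00259), the 1 called gene of 46 neurotransmitter receptors (median −0.04, adjusted p = 0.152). The potassium leak channel Ork1 fell 1.73-fold, the 1 called gene of 34 ion channels (median 0.01, adjusted p = 0.948). Of 34 neuropeptide genes, Proc rose 1.64-fold and CCHa2 fell 2.05-fold (4 when adjusted over the list alone, list adjusted p = 0.937). The neurotransmitter synthesis list (adjusted p = 0.846), the calcium handling list (0.845) and the list of CREB and activity-regulated genes (0.846) held no called gene. Among members of the first and last of these lists, Trhn had a log2 fold change of 0.60 ± 0.19 and kay of 0.26 ± 0.08, which passed without tau C and without tau B (adjusted p = 0.0288 and 0.0425). Of 16 clock genes, the photoreceptor cry fell 1.43-fold and the receptor gene Pdfr 1.30-fold (6 when adjusted over the list alone, list adjusted p = 0.617). The calls of cry, Pdfr and CCHa2 were lost with the yolk protein covariate (adjusted p = 0.239, 0.197 and 0.144). cry was also lost without the variance trend and without control E, control F and tau B, and Pdfr with rescaling to equal totals.

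Of 76 nuclear genes of oxidative phosphorylation, COX8 fell 1.56-fold and cype 1.42-fold, and 74 were not called (2 when adjusted over the list alone). The median was −0.15 (camera adjusted p = 0.000159), but adjusted p = 0.899 with an estimated correlation, 0.0815 without control C, where it was −0.06, and 0.707 with the yolk protein covariate, where it was −0.05. Array weights gave −0.09 and rescaling to equal totals −0.04. Of 85 cytosolic ribosomal proteins, 6 fell, 79 were not called and none rose (6 when adjusted over the list alone). RpS21 fell 1.82-fold, from 9271 ± 1996 to 5016 ± 508 (adjusted p = 0.000653), RpL38 2.08-fold, RpS2 1.61-fold and RpL41 1.63-fold. The median was −0.10 (camera adjusted p = 0.000325), but adjusted p = 0.899 with an estimated correlation and 0.169 without control C, where it was −0.03. It was −0.05 without tau E or with array weights and −0.16 without control E, control F and tau B, and turned to 0.01 when libraries were rescaled to equal totals. With the yolk protein covariate the median was 0.03 (adjusted p = 0.707), and COX8, cype, RpL38, RpS2 and RpL41 were lost (adjusted p from 0.122 to 0.269). The mean log2 value of these genes was 14.04 in control C, against 13.48 to 13.69 in the other controls. Mitochondrial ribosomal proteins (71 genes, mRpL37 called higher, adjusted p = 0.15) and the 13 mitochondrially encoded genes (none called, adjusted p = 0.574) were not called as lists. mRpL37 was lost without any single library except control B, control C, control E and tau E (adjusted p from 0.061 to 0.0931). Of 17 glycolytic genes, Ldh rose 1.67-fold and Pgk fell 1.38-fold (3 when adjusted over the list alone, list adjusted p = 0.0924). Ldh was lost without any single library except control B, control C, tau B and tau D (adjusted p up to 0.103), and Pgk without any except control C, control D and control F (up to 0.098).

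Called members of lists of other cell types went in both directions, and none of these lists was called. Of 28 muscle genes, 3 rose and none fell (3 when adjusted over the list alone): Act87E rose 1.53-fold, the sarcomere gene tn 1.36-fold and Act57B 1.30-fold, and the list was not called (median 0.05, adjusted p = 0.32). Act57B was lost without tau C (adjusted p = 0.0542), and Act87E and Act57B with the yolk protein covariate (0.0931 and 0.106). Of 29 glial markers, 4 fell and 1 rose (10 when adjusted over the list alone, list adjusted p = 0.701). The glutamate transporter Eaat1 fell 1.44-fold, the transporters rumpel and CG6126 fell 1.68-fold and 1.47-fold, and the septate junction gene Gli rose 1.32-fold. CG6126 was lost without control A or tau C (adjusted p up to 0.0638), Gli without control E, control F and tau B (0.0882), and Eaat1, rumpel and CG6126 with the yolk protein covariate (adjusted p from 0.102 to 0.277). Of 130 chemosensory genes, 4 fell and 2 rose (6 when adjusted over the list alone, list adjusted p = 0.846). The odorant binding protein genes Obp8a and Obp99d fell 2.95-fold and 2.77-fold, and Obp49a rose 1.43-fold, all 3 lost with the yolk protein covariate (adjusted p from 0.055 to 0.211). Obp56g fell 1.36-fold and was lost without control A, tau E or tau F (adjusted p up to 0.0657). Gut enzymes (20 genes) held no called member (adjusted p = 0.176).

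Among detoxification genes other than the P450 genes, the glutathione transferases GstE3, GstD9 and GstE14 fell 1.65-fold, 1.59-fold and 1.89-fold and GstT2 rose 1.66-fold, of 44 antioxidant genes (4 when adjusted over the list alone, list adjusted p = 0.408). GstE14 was lost without control A, control E, tau B, tau C, tau E or tau F (adjusted p up to 0.067), GstT2 without any single library except control B, control C and tau B (up to 0.115), and GstD9 with the yolk protein covariate (0.189). Of 30 UDP-glycosyltransferases, Ugt35B1 and Ugt37A3 fell 2-fold and 2.90-fold (2 when adjusted over the list alone, list adjusted p = 0.109), and Ugt37A3 was lost without control A, control C, control D, control F, tau B or tau F (up to 0.0785). Of 55 autophagy and lysosome genes, Atg4b rose 1.42-fold and VhaM9.7-a fell 1.48-fold (2 when adjusted over the list alone, list adjusted p = 0.938). Atg4b, VhaM9.7-a, Ugt35B1, Ugt37A3 and Smg5 were lost with the yolk protein covariate (adjusted p from 0.101 to 0.195). Smg5 rose 1.26-fold in the list of nonsense-mediated decay (12 genes, 3 when adjusted over the list alone, list adjusted p = 0.109), and was lost without tau E or tau F (up to 0.0522). No member was called among lipid metabolism (22 genes, 7 when adjusted over the list alone, adjusted p = 0.559), heterochromatin and small RNA silencing (30 genes, 0.455), nuclear envelope and actin (18 genes, 0.455), cell cycle (31 genes, 0.794), proteasome (40 genes, 0.794) and histones (30 genes, 0.937). The proteasome list had a median of −0.04 and a mean of 0.08. In these lists bmm had a log2 fold change of 0.59 ± 0.16 (adjusted p = 0.0501, and 0.012 to 0.0489 without control B, control F, tau A or tau E) and Su(var)2-HP2 of 0.20 ± 0.08 (adjusted p = 0.192).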

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

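The tests of explanations named here were chosen after the results were seen, except those of a uniform level in silent genes and of other splits of the libraries. Whether called genes cluster was a question fixed beforehand, but its bound was chosen afterwards. In 322 groups of 6 libraries, 26 had a highest or lowest library set apart from the others by most of the range, where chance gives about 1 in 20 (16.1). Control C held 10 of these.

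Among measures of whole libraries, tau A had 41.5 M estimated read pairs, where the other tau libraries had 25.8 to 29.3 M, and tau B had 24.7 reads per kb in silent genes, where the others had 1.38 to 2.71. The mean log2 value of antimicrobial peptides was 9.15 in tau B, below 10.44 to 10.88 in the other tau libraries. That of ribosomal proteins was 14.04 in control C, above 13.48 to 13.69 in the other controls, and 13.28 in tau E, below 13.50 to 13.61. Control C held 6.1 of Cyp12d1-d, which was at 0 in the other controls. It was low for Ku80 (40.3), Acp1 (13.3), Tab2 (2385) and Hdc (1468), and high for Gli (1832), Pgk (6652), mt:CoII (33888) and COX7AL2 (380). Tau A was low for Fad2 (13.4) and dl (2496) and high for Ldh (1821). Control E was high for BomBc1 (1452), TotC (4026) and His2B:CG33902 (103), a histone copy that shares reads with others and was at 0 in tau E. Control B was low for LpR2 (13533) and Jon65Aiv (12.5) and high for VGAT (1104). Tau E was high for Su(var)2-HP2 (3616), and control A for cpa (1565).

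Control E, control F and tau B held reads in genes silent elsewhere. Deeper sequencing is argued against, since these 3 libraries had 0.926 times the median estimated read pairs of the others but 7.69 times their level in silent genes. In these 3 libraries the top 1% of silent genes took at most 9.43% of silent-gene reads, where it took 22.5% to 59.8% in the other libraries. This argues against RNA of another tissue that is concentrated in few silent genes. RNA spread over many silent genes stays open, because it could give such a share too. Genomic DNA may be the source and stays open. The percent of silent genes above 0 lay at most 20.2 points below that of a uniform level per kb (35.6 to 63.5 points elsewhere), which missed by little the bound of 20 set beforehand, and the X chromosome had 0.855 times the autosomal level on average. No biological explanation was tested, since both genotypes were affected.

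Some P450 genes with large rises have similar copies, whose sequence identity was not checked here. For Cyp6a17, reads or sequence shared with Cyp6a23 may account for the rise, since their sum differed by 0.09 on the log2 scale, where 0.45 was expected had Cyp6a23 kept its control level. Opposite changes of both genes would give such a sum too, so this stays open. For Cyp12d1-d the sum of the copies differed by 0.55 and for Cyp4p2 by −0.30, with spreads too wide to decide. For Cyp12d1-d, Cyp4p2, Cyp6d2 and Cyp6a17, all 4 without overlap between genotypes, strain variants and an effect of tau cannot be told apart, because genotype and strain background go together in this design. This limit of the design holds for all 567 called genes, of which 303 had values without overlap. Blocks of neighbouring genes from another strain stay open among the called genes: 40 neighbouring pairs exceeded the 39 that 95% of 1000 random draws did not (permutation p = 0.033), while outside gene families, 31 lay under the bound of 38 (permutation p = 0.349).

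Of 16 haemocyte markers 8 fell, of 24 fat body markers 4 fell and of 3 yolk protein genes Yp2 passed the exact test without pairing, and the camera calls of their lists were lost with an estimated correlation (adjusted p = 0.109, 0.275 and 0.339). For the haemocyte genes the median was −0.66 with the yolk protein covariate, against −0.72 without it. Fewer female heads stay open for these genes, because yolk protein RNA is not a count of females. For fit they are argued against as the whole cause, since it fell by 1.40 more on the log2 scale than the yolk proteins (exact permutation p = 0.00216). A lower share of females may still account for part of its fall. For the fat body genes fewer female heads stay open too: the median shrank from −0.40 to −0.16 with the yolk protein covariate (adjusted p = 0.046). That covariate differs between the genotypes, and its 3 genes are among the 24. For the yolk proteins a lower share of females may explain the fall and cannot be told apart from lower expression, since the sexes were not counted per pool here. Of 4 male-biased genes 0 fell, which decides little, because only 339 of 10845 tested genes fell. A fall of all non-neural tissue by a common share is argued against, because the 28 muscle markers did not fall as a list. Their mean log2 fold change was 0.1, with 16 above 0 and 12 below (camera adjusted p = 0.32). Muscle minus haemocyte markers was 0.85 ± 0.18 higher in tau (exact permutation p = 0.00216). That contrast was chosen after the haemocyte fall was seen, so its p decides little, and muscle is only 1 such tissue. A biological effect of tau on blood cells or fat body stays open and untested.

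Other splits of the 12 libraries, 100 drawn at random with the real one included, made chance unlikely for the count of called genes, but did not exclude it. The real split gave 567 and the highest other 346, and 1 of 100 splits gave as many. Chance is unlikely too for genes changed at least 2-fold (172, highest other 95, 1 split), for genes lower in tau (339, highest other direction 316, 1 split) and for genes higher in tau (228, highest other direction 316, 2 splits). For the number of called lists chance stays open: the real split gave 13, the highest other 24, and 55 splits gave as many.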

How the results depend on the processing

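The yolk protein covariate, the fit without 3 libraries, background subtraction and the alternatives for the sex markers were chosen after the data were seen. The planned covariate from roX1 and roX2 was not run. Of the 102 named genes that were called, 38 were called under every alternative and none reversed. The count of called genes, 567, was 876 with array weights (424 higher) and 369 without a variance trend (212 lower). With rescaling to equal totals 525 genes were called higher. Without control E, control F and tau B it was 308 (138 higher, 170 lower), and the smaller number of libraries can lower it. With the yolk protein covariate it was 146 (54 higher, 92 lower, 75 at least 2-fold). That covariate itself differs between the genotypes, so that it takes part of their difference by construction, and 59 of the 102 named calls were lost. Without a variance trend 25 were lost, without control E, control F and tau B 30, without any one library 5 to 20, and under each of the other alternatives at most 5. The losses given gene by gene above are not all of these. Leaving out each library in turn gave 376 to 674 called genes, 147 to 242 higher, 222 to 446 lower and 1 to 4 sex markers past the threshold against 2 with all 12, with 136 to 208 genes changed at least 2-fold and 12 to 16 lists. Rescaling to equal totals left 1 sex marker. No list, 0 of 44, was called with an estimated correlation. The ribosomal protein median turned from −0.10 to 0.03 with the yolk protein covariate. The cause of the other shifts was not tested.

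With the letters as a replicate block 699 genes were called. Across all genes same-letter libraries did not pair: their correlations ran from −0.23 to 0.14, and 2 of 12 libraries correlated best with their own letter. The yolk protein genes were an exception, with correlations across the 6 letters of 0.88, 0.92 and 0.86 for Yp1, Yp2 and Yp3. They and fit (0.45) were lower in tau in all 6 letters, so that all 4 sex markers passed an exact sign-flip permutation test with the letters as a replicate block (exact permutation p = 0.0312 each, the smallest it can give). In the limma fit with that block Yp1, Yp2 and Yp3 passed (adjusted p = 0.0247, 0.00305 and 0.0178). Camera with its preset correlation gave the female-biased list an adjusted p of 6.1e-06 with that block. Without the block, that list's call was lost with an estimated correlation (camera adjusted p = 0.339). Whether the letters mark a shared batch is not given in the labels. Genes changed 1.5-fold were recovered in 8.9% of simulated cases at this spread.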

Other observations

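The lists of both groups here, and both tests, were chosen after the table of all genes had been seen. Cuticular hydrocarbons are made in oenocytes, cells under the cuticle. Only heads were sampled here, and which of their cells hold these RNAs was not tested. Of 21 tested genes of this synthesis 9 fell, 1 rose and 11 were not called. CG6660, CG10097, CG18609 and spidey fell, with log2 fold changes of −1.42, −1.98, −2.19 and −0.58 (adjusted p from 0.00054 to 0.0251). Desat1 was at −0.36 ± 0.18 and FASN2 at −0.30 ± 0.29, which did not pass (adjusted p = 0.302 and 0.659). wat rose by 0.36. Whether a lower signal of oenocytes may be present stays open: the mean of the 16 members that the rule for named genes had not picked differed by −0.68 on the log2 scale, but these genes were listed after their falls could be seen, so the value decides nothing.

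Enzymes of folate and glycine metabolism moved in both directions. Nmdmc, a mitochondrial folate enzyme, rose by 1.5 ± 0.25 on the log2 scale, from 1068 to 3014, Gnmt by 1.53 ± 0.36, CG3999 from 637 to 1546 and Mthfs by 0.93 ± 0.19, while CG6415 fell by 0.94 ± 0.23. Of 15 tested members 5 rose and 1 fell. A joint rise of these enzymes may exist but was not shown, since the list was also drawn up after the values could be seen. Its mean differed by 0.27 (exact permutation p = 0.149), and AsnS (0.07 ± 0.10) and Shmt (−0.10 ± 0.22) did not pass.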
